A study of Mus musculus with 8 samples.

How the data were processed

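RNA was purified from NIH3T3 cells with a column kit after at least 1 week of puromycin selection for a scrambled shRNA or shRNA against RPRD1B, and the labels state that the knockdown was checked by Western blot. Per the labels, cDNA was made with random hexamers, libraries were made with a low-input kit not described as stranded, and paired-end reads of 75 bases were sequenced on an Illumina NextSeq instrument. The labels name the mm10 genome build. The aligner, the counting tool, the gene annotation and the sequence targeted by the shRNA are not given in the sources used here.

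The 8 libraries were deposited as 2 sets of 4, each with raw counts per gene and a comparison by the authors. The deposited counts are whole numbers for 23420 entries in the same order in both sets, not normalised and not filtered, and they are the values used for every test. The deposited comparisons also list a signal, the mean over the 4 libraries of counts divided by size factors, with entries under a mean of 10 left out. They give a log2 fold change of knockdown over scrambled cells by the authors, with its standard error by the authors on the same log2 scale. The deposited q-value is the authors' adjusted p-value. The signal, fold changes and q-values of the authors' deposited table were set beside the results for comparison and not used in any test. No column of samples was left out. Of the 23420 entries, 27 are gene names that a spreadsheet turned into dates, which were kept in the totals and tests and are not named. Depth ranged from 12311442 to 23223139 counts, where 3 counts are 0.129 to 0.244 CPM.

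Genes with a mean count of at least 10 over the libraries of a fit were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test with robust settings on TMM-scaled counts, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Tests of genes, lists and correlations are two-sided, while the counts of splits and the test of neighbouring chromosome stretches are one-sided. The fit over 8 libraries had terms for the set and the group, the fits within a set had the group alone, and the difference between sets was the interaction of both. Standard errors were computed as the absolute log2 fold change over the square root of F. CPM values are TMM-scaled. For Rprd1b, labels were also exchanged within sets in an exact permutation test of all 36 assignments. The replicate numbers do not pair the libraries: deviations of libraries with the same number correlated across genes at 0.0208 in set 1 and -0.0450 in set 2. Other-tool calls were made with DESeq2 1.42.0. Coordinates are those of RefSeq GRCm38.p6, the assembly that mm10 names, where 23234 of 23393 gene names were found.

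The 31 gene lists, the naming rule and the comparisons were fixed before the data were examined. Lists with at least 5 tested genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists, and with a correlation estimated per list and with fry as alternatives. The lists cover RPRD relatives and CTD phosphatases, RNA polymerase II subunits, CTD kinases and elongation factors, 3-prime end processing, Wnt targets, G1/S, G2/M, homologous recombination, end joining, p53 targets, Hedgehog, interferon response, NF-kB and cytokines, collagens, contractile genes, immediate early genes, stress responses, NRF2 targets, cholesterol, fatty acids, glycolysis, ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes, histones, and markers of adipocytes, muscle, epithelium, endothelium, macrophages and neural cells. Some genes are in 2 lists.

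Named genes are Rprd1b, Rprd1a and Rprd2; the 12 largest rises and 12 largest falls among called genes with a mean count of at least 50, the same sign in both sets and both knockdown libraries on the same side of both scrambled libraries in each set; up to 4 members with the smallest p per list; and the 4 genes with the smallest p in each direction for the difference between sets. A total of 382 higher and 356 lower genes met the rule for size. Numbered gene models are counted but not named. Ptgs2, Txnrd1, Cdkn1a and Syn1, each the fifth called member of its list, and Kdm5d and Uty were added after their values were seen, and these 6 were not followed under the alternatives.

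The tests were tried on simulated data made from these counts. Over both sets 86.9% of genes shifted by a log2 fold of 0.5 and 93.9% of those shifted by 1 were called, and 9.18% of calls were false. Within set 1 these were 74.5%, 90.7% and 5.85%, within set 2 73.5%, 89.0% and 8.52%, and for the difference 53.5%, 78.8% and 3.68%. Camera found 2 of 2 lists shifted by 0.2 and called 0 of 23 unshifted lists. Genes were simulated independently of each other, so this does not test false calls of lists whose genes vary together. Alternatives were no filter, a mean count of at least 50, DESeq2 size factors, upper-quartile scaling, the DESeq2 test, a fold threshold, a block for the replicate number, no set term, each set alone and each library left out. Leaving out Rn45s, thinning to the smallest library, counting without the genes of chromosome Y and an imprinted region, and leaving out libraries for the difference between sets were added after seeing the data.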

Results

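RNA was sequenced from 8 libraries of NIH3T3 cells, a mouse embryonic fibroblast line, 4 from cells carrying a scrambled short hairpin RNA (shRNA) and 4 from cells carrying shRNA against RPRD1B. RPRD1B is a protein that binds the C-terminal domain (CTD) of the largest subunit of RNA polymerase II. The series asks how expression levels differ between control and knockdown cells. The libraries came as 2 sets, each with its own counts and its own deposited comparison: set 1 holds replicates 1 and 2 of each group, and set 2 holds replicates 3 and 4. The labels do not say what distinguishes the sets, or whether replicates are separate cultures, so the p-values measure the spread between libraries.

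The depth ranged from 12311442 to 23223139 counts per library. Scrambled replicates 1 to 4 held 13872603, 14032101, 16509243 and 12891676 counts, and RPRD1B replicates 1 to 4 held 14124534, 15225103, 12311442 and 23223139. Between 14033 and 14633 genes had a count in each library. A count of 0 allows a level of up to 0.129 to 0.244 CPM (the count as a part of the library total, on a common scale) at these depths, a floor that covers counting error only. Log2 CPM correlated across genes at 0.993 to 0.994 between replicates of a group within a set, at 0.991 to 0.992 between groups within a set, and at 0.952 to 0.958 between sets. Genes are not independent replicates, so these correlations carry no p. The first principal component held 76.7% of the variance and separated the sets, and the second held 6.91% and separated the groups. The set was a term in the fits over all 8 libraries unless stated otherwise.

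Rprd1b messenger RNA was lower in the knockdown libraries of both sets. In set 1 it stood at 43.4 ± 1.46 CPM in scrambled cells (SD, n = 2) and 27.2 ± 1.14 in knockdown cells, and in set 2 at 40.2 ± 0.956 and 22.6 ± 0.136. Over both sets the fitted log2 fold change was -0.75 ± 0.07 (SE) with an adjusted p of 4.14e-14, and the level fell by 40.5%. The gene lies on chromosome 2 at 158028475 to 158078207 (mm10). All 4 knockdown libraries lay below all 4 scrambled libraries. The exact two-sided permutation test within sets gave p = 0.0556, the smallest that its 36 assignments allow. The fold was -0.67 in set 1 and -0.83 in set 2 when each was fitted alone, and the difference of -0.16 ± 0.13 between them did not pass the test (adjusted p = 0.784). The authors' deposited table for set 1 lists a log2 fold change of -0.64 for Rprd1b (SE 0.10, q = 3.47e-08), and the authors' deposited table for set 2 lists -0.80 (SE 0.11, q = 2.84e-10).

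The paralog Rprd1a (chromosome 18, 24484960 to 24530235) and the related Rprd2 (chromosome 3, 95759871 to 95819744) gave no call. Rprd1a stood at -0.03 ± 0.09 (adjusted p = 0.900) and Rprd2 at -0.07 ± 0.05 (adjusted p = 0.457) on the log2 scale over the 8 libraries. Without scrambled replicate 2 or scrambled replicate 4 the sign of the Rprd1a value changed, at adjusted p = 0.993 and 0.988.

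**Figure D1:**
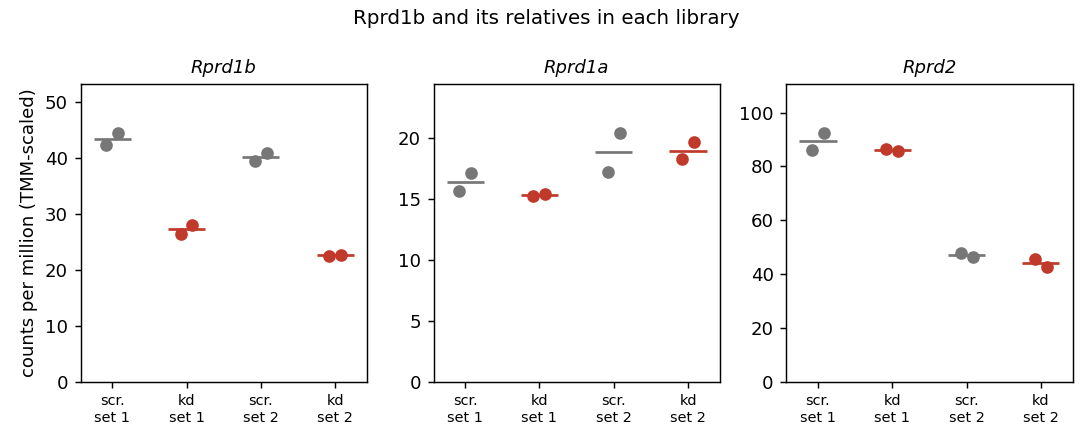
CPM, scaled by TMM (y axis), of Rprd1b, Rprd1a and Rprd2 in each of the 8 libraries, with scrambled libraries in grey and knockdown libraries in red. Points are libraries and lines are the means of n = 2; Rprd1b falls from means of 43.4 to 27.2 in set 1 and from 40.2 to 22.6 in set 2.

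The comparison over both sets asks which genes differ between knockdown and scrambled cells after the difference between sets is fitted. The knockdown cells had more RNA of Fam19a1, Rab6b, Scara5, Pde1a and Dcn, and less of Cyp1b1, Myzap, Galc and Sulf1. Fam19a1, which codes for a secreted protein of the TAFA family (chromosome 6, 96113154 to 96657204), rose most among the genes named by rule, from 3.34 ± 0.534 to 16.8 ± 0.912 CPM (SD, n = 4). Its log2 fold change was 2.34 ± 0.13 with an adjusted p of 1.23e-23. Dcn, the proteoglycan decorin that binds collagen fibrils (chromosome 10, 97479500 to 97518163), rose from 50.5 ± 6.50 to 143 ± 11.3 CPM, a log2 change of 1.49 ± 0.09 (adjusted p = 1.07e-05). Galc, the lysosomal galactosylceramidase (chromosome 12, 98202287 to 98259459), fell from 18.0 ± 3.37 to 9.13 ± 1.55 CPM, a log2 change of -0.98 ± 0.10 (adjusted p = 3.76e-11). Sulf1, an enzyme that removes sulfate from heparan sulfate (chromosome 1, 12692197 to 12861192), fell from 43.0 ± 1.74 to 27.1 ± 2.50 CPM, a log2 change of -0.66 ± 0.07 (adjusted p = 2.92e-12).

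The other large rises were of Rab6b, a small GTPase of vesicle traffic (2.00 ± 0.17), Scara5, a scavenger receptor that binds ferritin (1.83 ± 0.16), and Pde1a, a calcium- and calmodulin-dependent phosphodiesterase (1.68 ± 0.18). Next came Nov, a matricellular protein of the CCN family (1.44 ± 0.21), Flrt3 (1.30 ± 0.10), the inflammatory caspase Casp4 (1.26 ± 0.14) and Ppef1 (1.21 ± 0.20). Sema3c, a secreted semaphorin, rose by 1.12 ± 0.16, the adhesion protein Negr1 by 1.09 ± 0.12 and Rgs17, a regulator of G protein signalling, by 1.07 ± 0.11. Adjusted p-values of these 10 genes ran from 5.87e-17 for Flrt3 to 1.01e-05 for Ppef1. The remaining large falls were of Cyp1b1, a cytochrome P450 monooxygenase (-1.06 ± 0.19), Myzap (-1.03 ± 0.18), the kinase Tnik (-0.78 ± 0.14), Ankrd6 (-0.75 ± 0.16) and the zinc finger factor Ikzf2 (-0.70 ± 0.16). Slc40a1, the iron exporter ferroportin, stood at -0.67 ± 0.12 and Pi15 at -0.67 ± 0.08. Adjusted p-values of these 7 falls ran from 1.79e-09 for Pi15 to 0.00193 for Ikzf2. Each gene named for its size had both knockdown libraries on the same side of both scrambled libraries in each set. Tnik was lowest in RPRD1B replicate 2, at 4.21 CPM against 6.37 to 6.67 in the other 3 knockdown libraries.

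A pair of genes on chromosome Y was also among the largest falls, Ddx3y at -0.68 ± 0.05 (adjusted p = 7.92e-17) and Eif2s3y at -0.77 ± 0.08 (adjusted p = 5.21e-11). The other tested genes of this chromosome, Kdm5d and Uty, chosen after their values were seen, stood at -0.58 ± 0.09 (adjusted p = 2.37e-06) and -0.62 ± 0.12 (adjusted p = 0.000333). The weighted mean of these 4 genes was -0.68 ± 0.04. Medians of all tested genes also lay off 0 on 7 autosomes in both sets, from -0.06 on chromosome 12, which carries Galc, to 0.04 on chromosome 15, which carries Nov. Small called changes can be near the size of such a shift. The G2/M genes called below all lie on chromosome 11. Hmmr, at -0.12, lies in a 20 Mb stretch with a median of -0.09. Aurkb, at -0.16, and Top2a, at -0.10, lie in stretches with medians nearer 0, of -0.03 and -0.02. The tests of genes and lists were not corrected for these shifts.

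In all, 888 of 11723 tested genes passed an adjusted p of 0.05 in edgeR, 465 higher and 423 lower in the knockdown cells. Most changes were small: the median absolute log2 fold change of the called genes was 0.24, and 48 of them reached 1, 36 higher and 12 lower. Of the 888 genes, 880 had the same sign in both sets, and 792 had both knockdown libraries on the same side of both scrambled libraries in each set. These genes were called on the same libraries, so both counts follow in large part from the selection and are no replication. Chance gives such a separation to 5.56% of genes, and 1924 of all tested genes (16.4%) showed it. DESeq2 called 304 higher and 318 lower genes, and without the set term edgeR called 18 genes, among them 11 of the 73 named genes called here. In the simulated data 9.18% of edgeR calls over both sets were false, above the 0.05 that the threshold sets.

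Of the 31 gene lists fixed before the data were examined, 25 had at least 5 tested genes, and 5 of these passed camera, a competitive set test with a preset correlation of 0.01. None of the 5 calls held with a correlation estimated per list. Fry, a test of whether the genes of a list move one way on balance, also called 3 of these lists. They were the contractile, NF-kB and homologous recombination lists, each at an adjusted p of 0.0133. The estimated correlation was -0.0106 for the NF-kB list and -0.0110 for the homologous recombination list, under the preset value. A higher correlation therefore did not end these calls in camera, and what did was not tested. For the contractile, collagen and oxidative phosphorylation lists the estimated correlation was 0.0436 to 0.114.

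Contractile genes and targets of SRF and YAP, the factors that respond to actin dynamics and cell tension, were lower in the knockdown cells. Of 22 tested members 9 fell and 0 rose, and 11 fell when adjusted over the list alone. The smooth muscle actin gene Acta2 fell from 762 ± 256 to 631 ± 225 CPM (SD, n = 4, most of it between sets), a log2 change of -0.28 ± 0.03 (adjusted p = 1.27e-09). Tagln, an actin-binding protein of smooth muscle, changed by -0.45 ± 0.07, and the YAP targets Amotl2 and Ankrd1 by -0.26 ± 0.05 and -0.26 ± 0.06. The list had a median of -0.09 and an adjusted p of 2.19e-07 in camera, and an adjusted p = 0.153 with an estimated correlation.

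NF-kB targets and cytokines were higher in the knockdown cells. Of 20 tested members 4 rose and 1 fell, and 6 rose and 1 fell when adjusted over the list alone. The monocyte chemokines Ccl7 and Ccl2 rose by 0.69 ± 0.08 (adjusted p = 3.70e-09) and 0.40 ± 0.05 (adjusted p = 3.69e-08), and the cytokine Lif by 0.49 ± 0.08 (adjusted p = 4.78e-06). The neutrophil chemokine Cxcl1 rose by 0.44 ± 0.12 (adjusted p = 0.0128), a call that was lost without scrambled replicate 1 (0.0610), scrambled replicate 4 (0.138) or RPRD1B replicate 2 (0.0573). Ptgs2, the inducible cyclooxygenase, was the member that fell, at -0.12 ± 0.03 (adjusted p = 0.0238). The list had a median of 0.15 and an adjusted p of 0.000162 in camera, and an adjusted p = 0.111 with an estimated correlation. It was not called without the set term.

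Genes of homologous recombination and the Fanconi pathway lay slightly lower as a list, with 24 of 30 tested members below 0 and a median of -0.11. A single member, Brca2, passed the test of single genes, at -0.20 ± 0.06 (adjusted p = 0.0164), and 1 fell when adjusted over the list alone. Its call was lost without RPRD1B replicate 2 (0.0671) or RPRD1B replicate 4 (0.0856). The list had an adjusted p of 0.00215 in camera, and an adjusted p = 0.111 with an estimated correlation.

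Collagens and other extracellular matrix genes went both ways. Of 27 tested members 14 fell and 4 rose, and 16 fell and 4 rose when adjusted over the list alone. Fibrillar Col3a1 rose by 0.46 ± 0.04 (adjusted p = 1.97e-14), from 119 ± 4.66 to 164 ± 6.90 CPM (SD, n = 4), beside Dcn. The elastic fibre protein Fbln5 fell by 0.26 on the log2 scale (SE 0.04), and the collagen VI chains Col6a1 and Col6a2 each stood at -0.23 ± 0.03. The median was -0.12, and the adjusted p was 0.00546 in camera, 0.0727 in fry and adjusted p = 0.554 with an estimated correlation. The list's call was lost without scrambled replicate 3 (0.131) or RPRD1B replicate 3 (0.241), and in set 1 alone (0.0914).

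Nuclear-encoded genes of oxidative phosphorylation had a median of 0.07, with 21 of 26 tested members above 0. Of these members 1 rose, Atp5a1 at 0.10 ± 0.03 (adjusted p = 0.0341), and 0 when adjusted over the list alone. The list had an adjusted p of 0.0396 in camera, 0.0886 in fry and adjusted p = 0.554 with an estimated correlation. It was lost without scrambled replicate 1 (0.157), scrambled replicate 4 (0.0671), RPRD1B replicate 1 (0.0783), RPRD1B replicate 2 (0.101) or RPRD1B replicate 4 (0.0822), and in set 2 alone (0.583). The call of Atp5a1 was lost without scrambled replicates 1 and 2 or RPRD1B replicates 1, 2 and 4, each left out alone (0.0651 to 0.209).

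**Figure D2:**
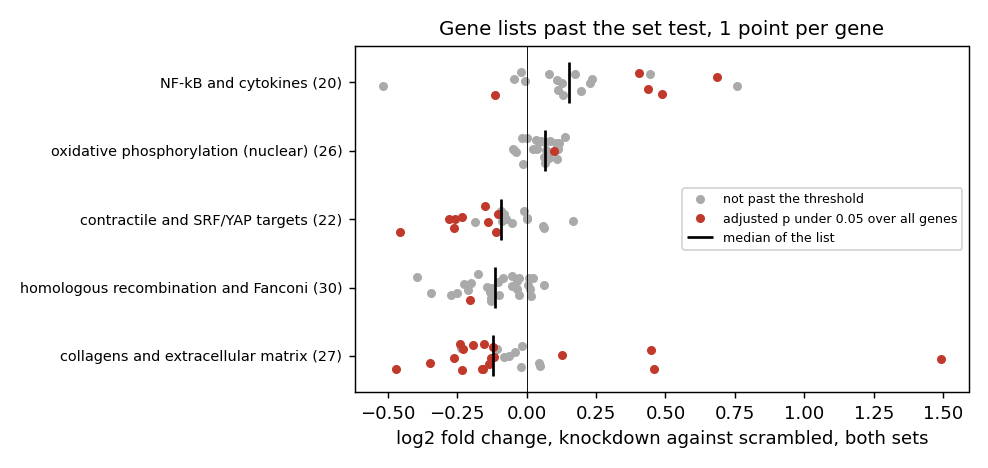
Log2 fold change of each tested member (x axis, knockdown against scrambled cells over both sets) of the 5 lists that passed the set test (y axis, tested members in brackets). Red points passed an adjusted p of 0.05 over all genes, grey points did not, and black lines are medians, which run from -0.12 for the collagen list to 0.15 for the NF-kB list.

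Genes of transcription and its CTD, the machinery that RPRD1B acts on, showed few changes. Of 12 tested RPRD relatives and CTD phosphatases, a list without Rprd1b itself, 1 fell, Ctdspl2 at -0.14 ± 0.04 (adjusted p = 0.0311), and 1 rose and 1 fell when adjusted over the list alone. The set test of that list gave an adjusted p of 0.542. None of 12 RNA polymerase II subunits passed, over all genes or over the list alone, and the median was 0.06 (adjusted p = 0.542). Of 26 CTD kinases and elongation factors 1 rose, Rtf1 at 0.11 ± 0.04, and 1 fell, Mnat1 at -0.19 ± 0.05, against 3 and 2 over the list alone (adjusted p = 0.830). Sympk, a scaffold of the 3-prime cleavage machinery, rose by 0.22 ± 0.05 (adjusted p = 0.00278) and was the 1 member of 18 in its list to pass either way (adjusted p = 0.830). Calls were lost for Ctdspl2 without scrambled replicates 1 and 4 or RPRD1B replicates 1 and 3 (0.0710 to 0.184), for Mnat1 without scrambled replicates 3 and 4 or RPRD1B replicate 4 (0.0613 to 0.184), and for Rtf1 when any library other than scrambled replicate 2 was left out (0.0673 to 0.243). Here and below each library was left out alone.

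Growth and cell cycle lists gave no set call. Of 12 tested Wnt targets 2 fell and 0 rose, and the same counts held when adjusted over the list alone (set test adjusted p = 0.542). They were Myc at -0.15 ± 0.04 (adjusted p = 0.00550), lost without scrambled replicate 2 (0.0682) or RPRD1B replicate 1 (0.0953), and Wisp1 at -0.15 ± 0.05, lost when any library other than scrambled replicate 2 and RPRD1B replicate 2 was left out (0.0652 to 0.160). Of 28 G1/S genes 1 rose, Gins2 at 0.16 ± 0.05, and 0 over the list alone (0.798); its call was lost without scrambled replicates 1, 2 and 4 or RPRD1B replicates 1 and 2 (0.0777 to 0.166). Of 25 G2/M genes 3 fell, and 5 over the list alone (0.431). These were Top2a at -0.10 ± 0.03, lost without scrambled replicates 3 and 4 or RPRD1B replicate 4 (0.0823 to 0.159), Hmmr at -0.12 ± 0.04, lost without scrambled replicates 1 and 3 or RPRD1B replicates 2, 3 and 4 (0.0601 to 0.136), and Aurkb at -0.16 ± 0.05, lost without scrambled replicates 1 and 2 or RPRD1B replicates 1, 2 and 4 (0.0556 to 0.281). Of 11 end-joining genes 1 fell, Polm at -0.26 ± 0.08, against 1 higher and 1 lower over the list alone (0.798); its call was lost without scrambled replicate 2 (0.168), scrambled replicate 4 (0.0508) or RPRD1B replicate 2 (0.123).

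Targets of p53 went both ways, with 2 of 25 higher and 3 lower, and 2 and 5 when adjusted over the list alone. Ei24 fell by 0.41 on the log2 scale (SE 0.06, adjusted p = 3.22e-07), Btg2, an antiproliferative gene also in the immediate early list, stood at -0.28 ± 0.05 and Zmat3 at -0.15 ± 0.04. Mdm2, the ubiquitin ligase of p53, rose by 0.13 ± 0.03, a call lost without scrambled replicate 2 (0.0600), scrambled replicate 3 (0.0520) or RPRD1B replicate 3 (0.0804), and Cdkn1a, the inhibitor p21, by 0.11 ± 0.03. The median was 0.03 while the set test pointed down (adjusted p = 0.542). Of 23 immediate early genes 1 rose, Zfp36 at 0.24 ± 0.05 (adjusted p = 0.00175), and 2 fell, Btg2 and Myc, against 2 and 4 over the list alone (0.731). Of 10 Hedgehog genes 0 rose and 2 fell, the co-receptors Cdon (-0.26 ± 0.07, lost without RPRD1B replicate 4 at 0.0702) and Boc, against 1 and 3 over the list alone (0.308). Boc stood at -1.01 ± 0.33 over both sets, with -1.87 ± 0.40 in set 1 (adjusted p = 0.000437) and -0.03 ± 0.48 in set 2 (adjusted p = 0.990), a difference of 1.85 ± 0.63 that did not pass the test (adjusted p = 0.309). Without scrambled replicate 2 it was -0.63, and the call was lost without scrambled replicates 1, 2 and 4 or RPRD1B replicates 1 and 2 (0.0635 to 0.353). None of 15 interferon response genes passed, over all genes or over the list alone (0.717).

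Among stress and metabolic lists, NRF2 targets had 4 of 19 members higher and 1 lower, and 5 and 1 over the list alone. The glutathione transferases Gsta4 and Gstm1 rose by 0.37 ± 0.04 (adjusted p = 5.81e-11) and 0.15 ± 0.03, ferritin heavy chain Fth1 by 0.19 ± 0.03 and the cystine transporter Slc7a11 by 0.34 ± 0.08, while Txnrd1 fell by 0.11 on the log2 scale (SE 0.03). The NRF2 median of -0.02 had the other sign than its set test (adjusted p = 0.431). Of 30 genes of the integrated stress and unfolded protein responses 2 rose, Slc7a11 and Cebpg (0.20 ± 0.04), and 2 fell, against 3 and 4 over the list alone (0.542). The falls were Psat1 at -0.12 ± 0.03, lost without scrambled replicate 3 (0.0520), and Xbp1 at -0.20 ± 0.05, lost without scrambled replicate 3 (0.0630) or RPRD1B replicate 4 (0.0503). Of 24 glycolysis and hypoxia genes 3 fell, also over the list alone (0.228): P4ha2 at -0.19 ± 0.05, Hk2 at -0.14 ± 0.04, lost without RPRD1B replicate 4 (0.0578), and Slc2a1 at -0.09 ± 0.03, lost without 6 libraries (0.0573 to 0.237), all but scrambled replicate 4 and RPRD1B replicate 4. Of 24 fatty acid genes the elongase Elovl6 alone passed, at -0.19 ± 0.04 (adjusted p = 0.000411), also over the list alone (0.553). Of 23 cholesterol synthesis genes 2 rose, also over the list alone (0.553). They were Dhcr7 at 0.27 ± 0.08, lost without scrambled replicates 1 and 3 or RPRD1B replicates 3 and 4 (0.0720 to 0.115), and Sqle at 0.10 ± 0.03, lost when any library other than scrambled replicate 2 and RPRD1B replicate 1 was left out (0.0768 to 0.155). None of 30 ribosomal protein genes (0.830) and none of 22 replication-dependent histone genes (0.422) passed, over all genes or over the list alone.

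Markers of other cell types were mostly near or under the count minimum. None of 14 epithelial markers was tested, and 2 adipocyte, 3 muscle and 2 endothelial markers were tested with 0 calls, over all genes or over the list alone. Of 3 tested macrophage and blood markers 1 rose, also over the list alone: Cd14, at 0.85 ± 0.26 (adjusted p = 0.0249), which was lost without scrambled replicates 1, 2 and 3 or RPRD1B replicates 2 and 4 (0.0547 to 0.117). Of 6 tested neural markers 3 rose and 2 fell, also over the list alone. The adhesion protein Ncam1 fell from 141 ± 3.06 to 94.8 ± 3.89 CPM (SD, n = 4), a log2 change of -0.57 ± 0.04 (adjusted p = 7.93e-18), and nestin (Nes) stood at -0.52 ± 0.09. The microtubule-associated Map2 rose by 0.81 ± 0.10, Syn1 by 0.24 ± 0.07 and Snap25 by 0.42 ± 0.11, the last lost without scrambled replicate 3 (0.0845) or RPRD1B replicate 3 (0.0754). The neural median was 0.33 while the set test pointed down (adjusted p = 0.798). None of the 15 mitochondrially encoded genes was among the gene names of the counts, so that list was not tested. DESeq2 did not call Ctdspl2, Mnat1, Rtf1, Gins2, Aurkb, Boc, Cd14, Polm, Atp5a1, Wisp1 or Dhcr7 (adjusted p 0.0530 to 0.150). Calls also ended for Slc2a1 and Wisp1 with no filter on low counts, for Sqle and Rtf1 with upper-quartile scaling, and for Mnat1, Boc, Brca2, Cd14, Polm, Atp5a1 and Ctdspl2 with counts thinned to the smallest library.

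Within set 1, which compares 2 knockdown with 2 scrambled libraries, edgeR called 563 of 11585 genes, 311 higher and 252 lower. Fam19a1 rose by 2.41 ± 0.19, Dcn by 1.72 ± 0.07 and Rab6b by 1.86 ± 0.23 on the log2 scale, and Galc stood at -0.98 ± 0.14 (adjusted p = 1.06e-08). Within set 2, with the same numbers of libraries, 611 of 11779 genes were called, 300 higher and 311 lower. There Fam19a1 rose by 2.27 ± 0.18, Dcn by 1.28 ± 0.06 and Rab6b by 2.16 ± 0.28, and Galc stood at -0.97 ± 0.15 (adjusted p = 5.73e-08). DESeq2 called 140 genes in set 1 and 184 in set 2. The set 1 count fell to 113 without RPRD1B replicate 1 and 145 without RPRD1B replicate 2, and the set 2 count to 304, 355, 354 and 273 without scrambled replicates 3 and 4 and RPRD1B replicates 3 and 4. With q under 0.05, the authors' deposited table lists 284 genes (163 higher, 121 lower) for set 1 and 238 (117 higher, 121 lower) for set 2. Of these genes of the authors' deposited table, edgeR also called 282 and 238.

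The sets share no library, so their fold changes can be compared. The labels do not say whether both sets came from the same selected cells. If they did, any lasting difference between the cells of the 2 groups would recur in both sets, whether or not the knockdown caused it. Over 11427 genes tested in both, the log2 fold changes correlated at Pearson r = 0.311 and Spearman rho = 0.253 across genes, which are not independent replicates. Of 954 genes called in either set, 782 had the same sign in both (82.0%, 95% Clopper-Pearson interval 79.4 to 84.4), against 58.9% of all genes. That interval treats genes as independent, which they are not, so it may be too narrow. Both sets called 111 genes higher, where chance gives 7.95, and 91 lower, where chance gives 6.74. In 5 genes the called directions were opposite. The correlation was 0.0380 with no filter on low counts and 0.438 with a mean count of at least 50.

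**Figure D3:**
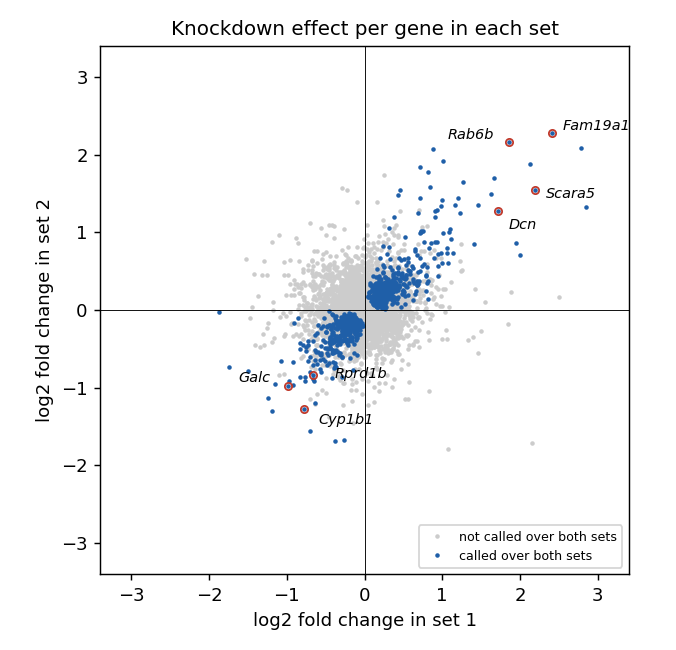
Log2 fold change, knockdown against scrambled cells, of 11427 genes in set 1 (x axis) and set 2 (y axis). Blue points passed an adjusted p of 0.05 over both sets and grey points did not; red circles mark named genes, such as Fam19a1 at 2.41 and 2.27, and 0 genes lie outside the axes.

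The last comparison asks whether the knockdown effect differs between the sets. Linker histone genes, the RNA component of RNase MRP and the matricellular gene Cyr61 had a more positive knockdown effect in set 2, and the aryl hydrocarbon receptor gene Ahr and Dcn a less positive one. Hist1h1e (chromosome 13, 23621777 to 23622558) stood at -0.12 ± 0.05 in set 1 and 0.49 ± 0.05 in set 2, a difference of 0.62 ± 0.08 (adjusted p = 0.000271). Rmrp (chromosome 4, 43492785 to 43493059) stood at -0.79 ± 0.11 and 0.17 ± 0.11, a difference of 0.96 ± 0.16 (adjusted p = 0.000271). Hist1h1c stood at -0.29 and 0.37, a difference of 0.67 ± 0.13 (adjusted p = 0.00356) that was lost without scrambled replicate 3 (0.125) or RPRD1B replicate 3 (0.0644). Cyr61, a YAP target, stood at -0.38 and -0.10, a difference of 0.29 ± 0.05 lost without RPRD1B replicate 1 (0.0932) or RPRD1B replicate 4 (0.0602). Ahr stood at 0.62 and 0.13, a difference of -0.48 ± 0.10 lost without scrambled replicate 3 (0.108), RPRD1B replicate 1 (0.135) or RPRD1B replicate 4 (0.0614). Dcn differed by -0.44 ± 0.09, lost without scrambled replicate 1 (0.103), scrambled replicate 3 (0.346), RPRD1B replicate 2 (0.148) or RPRD1B replicate 3 (0.0845). The differences of Dhx38 (-0.57 ± 0.13, from 0.28 to -0.30) and Fam168b (-0.28 ± 0.06, from 0.06 to -0.23) were lost without 6 and 7 of the 8 libraries (0.0644 to 0.156). The calls stayed without scrambled replicate 2 or 3 for Dhx38 and without scrambled replicate 2 for Fam168b.

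In all, 29 of 11723 genes passed the test of the difference, 20 more positive in set 2 and 9 less, with 1013 at an unadjusted p under 0.05. DESeq2 called 5 genes, among the named ones Hist1h1e, Rmrp and Cyr61. The count was 7 without scrambled replicate 3, 10 without RPRD1B replicate 1 or RPRD1B replicate 3, 13 without RPRD1B replicate 4, 53 without scrambled replicate 2 and 50 with no filter on low counts. Among the lists, the replication-dependent histones had a more positive knockdown effect in set 2, with a median difference of 0.49 over 22 tested genes (adjusted p = 1.70e-07, and adjusted p = 0.333 with an estimated correlation). Beside them, the ribosomal RNA precursor Rn45s, the most abundant feature, stood at -0.46 in set 1 and 0.46 in set 2, a difference of 0.92 ± 0.31 (adjusted p = 0.532). The nuclear RNA Malat1 stood at -0.34 ± 0.05 (adjusted p = 0.000288) in set 1 and 0.01 ± 0.05 (adjusted p = 0.963) in set 2. Malat1 was not among the 29 genes called for the difference. Interferon response genes had a median difference of -0.25 (adjusted p = 0.00819, and adjusted p = 0.333 with an estimated correlation), immediate early genes 0.13 (0.0216, and adjusted p = 0.917 with an estimated correlation) and cholesterol synthesis genes -0.06 (0.0306, and adjusted p = 0.333 with an estimated correlation).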

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

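All tests of explanations in this part were chosen after the result was seen, except that of a single aberrant library for the histones and the count of other label assignments.

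Tnik stood at 4.21 CPM in RPRD1B replicate 2 and at 6.37 to 6.67 CPM in the other 3 knockdown libraries, a gap of 0.876 of the group's range. It was the 1 group far from the others among 72 groups of 4 libraries over 36 measures, where chance gives about 1 in 20. Each group spans both sets, which differ in many genes, so that rate may not hold here.

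The difference of the knockdown effect between sets was called for 29 genes. The 18 assignments of the labels within the sets are too few for a share under 0.05. In these, 2 gave as many genes, the real one with 29 and the one that exchanges the labels in a single set with 1037. That assignment turns the knockdown effect itself into a difference between sets, so its count points to the structure of the samples. The other 16 gave 0 to 2 genes. Each of them mixes knockdown and scrambled libraries within a set, so the real effect counts as spread, which keeps their counts low.

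The genes named for this difference, set 2 minus set 1 on the log2 scale, were Hist1h1e at 0.62, Rmrp at 0.96, Hist1h1c at 0.67, Cyr61 at 0.29, Ahr at -0.48, Dcn at -0.44, Dhx38 at -0.57 and Fam168b at -0.28. Hist1h1e and Rmrp kept the call whichever library was left out, and the other 6 lost it without at least 1 library: Hist1h1c without scrambled replicate 3 (0.125) or RPRD1B replicate 3 (0.0644), Cyr61 without RPRD1B replicate 1 (0.0932) or RPRD1B replicate 4 (0.0602), Ahr without scrambled replicate 3 (0.108) or RPRD1B replicates 1 and 4 (0.135 and 0.0614). Dcn lost it without scrambled replicates 1 and 3 or RPRD1B replicates 2 and 3 (0.0845 to 0.346), Dhx38 without any library other than scrambled replicates 2 and 3 (0.0644 to 0.156), and Fam168b without any other than scrambled replicate 2 (0.0709 to 0.131). Among the lists, the median difference was -0.25 for interferon response genes, 0.13 for immediate early genes, -0.0553 for cholesterol synthesis genes and 0.49 for replication-dependent histones, and none of these calls held with an estimated correlation (adjusted p 0.333 to 0.917).

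The 22 replication-dependent histones had a more positive knockdown effect in set 2, by a median of 0.49, and 19 of them had a positive difference. A single aberrant library is argued against, since the lowest median with 1 library left out was 0.40. A change in the share of cells in S phase stays open: the G1/S genes had a median difference of 0.00936 (95% interval -0.0669 to 0.0640), but they went both ways, from -0.67 to 0.35 with an SD of 0.21, so their median does not decide it. Other RNAs without a poly(A) tail moved the same way, with 25 of 26 positive and a median of 0.40 (0.28 to 0.84). Of these 26, 1 was called for the difference, Rmrp, which had already been named for it. A yield of such RNAs that differs by group and set may account for the histones too. Both intervals in this paragraph come from resampling genes. They leave out the spread between libraries and treat genes as independent. No other biological explanation was tested, since the labels do not say how the sets differ.

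Genes on chromosome Y were lower in the knockdown cells with a weighted mean log2 change of -0.68 ± 0.04, or 37.5% less. Reads shared with the copies on chromosome X are argued against: reads lost from the Y genes would raise those copies by a known amount, and the slope of the observed on that amount was -0.0193 (95% interval -0.381 to 0.343). A share of knockdown cells without chromosome Y lowers all these genes alike, and their folds did not differ beyond their fitted errors by Cochran's Q, with a p of 0.429. This explanation stays open, and the difference between sets was -0.06 ± 0.07. An effect of RPRD1B on these genes was not tested apart from it.

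In an imprinted region of chromosome 12 (109452485 to 110281097), chosen after its values were seen, Rian stood at -0.57 ± 0.04, Rtl1 at -0.65 ± 0.09, Meg3 at -0.56 ± 0.09 and Mirg at -0.39 ± 0.08, and Dlk1 at 0.01 ± 0.03; these genes overlap in part and the libraries were not described as stranded. Fewer copies of this end of the chromosome are argued against, since 40 tested genes within 2 Mb had a median of -0.0212 (95% interval -0.0840 to -0.0119), with 1 called. That interval comes from resampling genes and leaves out the spread between libraries. A lower yield of nuclear RNA may account for part of the fall in set 1. There other nuclear long non-coding RNAs had a mean of -0.25 (-0.41 to -0.10) and Meg3 stood at -0.72. They were Malat1 (-0.34), Neat1 (-0.38), Tug1 (-0.10) and the imprinted Kcnq1ot1 (-0.49), Airn (-0.14) and Peg13 (-0.00279). With imprinted RNAs among them, the mean in set 1 does not separate a lower yield from a change of imprinted expression. In set 2 these nuclear RNAs had a mean of -0.00600 (-0.0589 to 0.0469), which argues against a lower yield there. Meg3 stood at -0.40, Rian at -0.54 and Rtl1 at -0.52 in that set, while Mirg, at -0.28, was not called there (adjusted p = 0.194). The fall of Meg3 was smaller in set 2, and Meg3 was among the genes called for the difference between sets (0.33, adjusted p = 0.0342). A change of imprinted expression in the knockdown cells is a hypothesis that these data leave open and did not test.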

How the results depend on the processing

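The alternatives added after seeing the data were without Rn45s, thinned to the smallest library, the count without genes of chromosome Y and the imprinted region, and each library left out for the difference between sets. Rprd1b kept its direction and its call in each alternative run for it, which leaves out the fold threshold that its value does not reach, from -0.79 to -0.73 with a library left out and at -0.75 (adjusted p = 0.0492) with no set term. The DESeq2 test called 304 higher genes over both sets, 140 in set 1, 184 in set 2 and 5 for the difference, and the cause was not tested. With an absolute log2 fold change of at least 1 there were 48 genes (36 higher, 12 lower), 43 in set 1, 56 in set 2 and 3 for the difference, as a stricter threshold gives. With no set term 18 genes were called (12 higher, 6 lower), since the spread between sets then counts as error. With no filter on low counts the difference was called for 50 genes, the cause of which was not tested. Camera with an estimated correlation called 0 lists, and fry 3. The correlation between sets was 0.0380 with no filter, which adds genes with few counts, and 0.438 with a mean count of at least 50. With a library left out, which leaves fewer samples, the calls ran from 113 to 571 in set 1, from 273 to 355 in set 2 and from 7 to 53 for the difference; a lone library of a group is then assumed to vary like the others. Over both sets it gave at least 625 calls, and 4 to 6 lists. Other filters and scalings gave 870 to 928 genes over both sets, the block for the replicate number 846, without Rn45s 902, thinned 819, and without the genes of chromosome Y and the imprinted region 880. Rprd1a ran from -0.0967 to 0.00700 with a library left out and reversed in sign without scrambled replicate 2 (0.00269) and scrambled replicate 4 (0.00700), values far under its error of 0.09; the cause was not tested. For 75 named genes, 1093 of 1273 alternatives kept direction and side of the threshold, 178 lost the call and 2 reversed. In every alternative 12 genes kept both, among them Rprd2, which was not called to begin with. For the 8 genes of the difference, 90 of 120 alternatives kept direction and call and 30 lost the call. A pseudocount and recovered reads did not apply, since the files hold raw counts, and DESeq2 has no list test. At these depths genes under a mean of 10 counts were not tested.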

Other observations

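In this part the tests of whole chromosomes and of chromosome stretches were chosen after the result was seen. The comparison of the sets was made without alternatives other than the estimated correlation for its lists. Its genes named below were chosen after their values were seen.

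Cells of set 2 differed from those of set 1 far more than knockdown from scrambled cells, in both groups alike as fitted. Of 11723 genes 3874 were higher and 3855 lower in set 2, and 1333 of these changed by at least 1 on the log2 scale. Targets of p53 were higher, with 17 of 25 up and 4 down and a median of 0.77, among them Trp53inp1 at 3.38 ± 0.08, Mdm2 at 2.04 ± 0.03 and Cdkn1a at 1.16 ± 0.03. The p53 list had an adjusted p of 1.25e-09 in camera and of 0.0320 with an estimated correlation, the 1 list here that held with it. Immediate early genes were higher too, with 16 of 23 up and 5 down and a median of 1.15, led by Fos at 3.23 ± 0.12 and Dusp1 at 2.89 ± 0.05 (adjusted p = 2.19e-10, and adjusted p = 0.165 with an estimated correlation). Interferon response genes had 8 up and 1 down and a median of 0.63, among them Irf1 at 2.85 ± 0.12 and Stat2 at 2.28 ± 0.08 (adjusted p = 0.0102, and adjusted p = 0.239 with an estimated correlation).

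Cholesterol synthesis genes were higher in set 2, with 19 of 23 up and 1 down and a median of 0.56, among them Dhcr7 at 1.65 ± 0.08 and Hsd17b7 at 1.24 ± 0.04 (adjusted p = 2.02e-08, and adjusted p = 0.157 with an estimated correlation). Replication-dependent histones were lower, with 21 of 22 down and a median of -2.14, among them Hist1h2be at -3.55 ± 0.11 (adjusted p = 1.79e-12, and adjusted p = 0.165 with an estimated correlation). Contractile genes and SRF and YAP targets were lower, with 17 of 22 down and 3 up and a median of -0.45, among them Tagln at -1.49 ± 0.07 and Ankrd1 at -1.27 ± 0.06 (adjusted p = 7.61e-06, and adjusted p = 0.165 with an estimated correlation). What distinguishes the sets is not given in the sources used here. Whether it is a batch or a difference in treatment or culture was not tested, and each group spans both sets.

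Other splits of the 8 libraries into 4 and 4 were counted for the 888 genes called between knockdown and scrambled cells and for the 7729 called between sets. In each case 1 of 34 splits, the real one, gave as many genes, and the highest of the others gave 0. A further split, equal to the other factor, could not be fitted. The other splits mix the real groups, so the real effect counts as spread in them, which keeps their counts low. Splits that keep the other factor balanced number 18, too few for a share under 0.05.

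Long genes could respond differently to the loss of a factor of RNA polymerase II. The rank correlation of log2 fold change and gene length over 11366 genes was -0.0103 (permutation p = 0.269), with 0.0234 in set 1 and -0.0412 in set 2, which argues against a shift of long genes in 1 direction. A signed correlation does not see a change in both directions. The median length was 35.1 kb for genes called higher and 42.8 kb for genes called lower, against 23.1 kb for all tested genes, so a relation of length to being called, in either direction, stays open and was not tested.

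Medians of chromosomes shifted slightly between knockdown and scrambled cells, and called genes leaned with them. Chromosome 12 had 4 genes called higher and 32 lower, chromosome 11 had 36 and 83, and chromosome 1 had 20 and 48. On chromosomes 2, 7, 10 and 15 the counts were 48 and 19, 41 and 20, 41 and 11, and 33 and 9. On 7 of 19 autosomes (1, 2, 7, 10, 11, 12 and 15) the median log2 fold change lay outside 95% of 1000 random gene lists after adjustment. This held in the same direction in both sets, and the medians ran from -0.06 on chromosome 12 to 0.04 on chromosome 15. The smallest p that the lists can give was 0.001, and 0.0029 after adjustment. Chromosome 2 in set 1 stood at 0.005, and 0.012 after adjustment. Neighbouring stretches of 20 Mb shifted alike, with r = 0.586 between the medians of neighbouring windows against 0.162 at the upper 95% limit of shuffled genes. By set the r was 0.416 and 0.535. Of 53 windows on the 7 chromosomes, 47 had the sign of their chromosome. Their own genes gave the chromosome its sign, so a high count follows in part from the selection. On chromosome 7 it was 4 of 8: the windows at 0 to 40 Mb stood at 0.08 and 0.10, while the lowest window stood at -0.02. On chromosome 11 it was 6 of 7: the first 3 windows stood at -0.10, -0.11 and -0.09 and the last, which was the lowest, at -0.14, while the highest stood at 0.06. A candidate explanation is that the cells of the 2 groups differ in copy number of chromosomes or segments, as sublines of a cell line may, and the values fit that. Neighbouring genes regulated together would give the same pattern, and the counts alone do not separate these.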
